A study of Caenorhabditis elegans with 36 samples.

How the data were processed

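Whole-body RNA of Caenorhabditis elegans was profiled in 36 libraries, 3 for each of 12 groups formed by RNAi arm (elt-2 RNAi or empty vector, which the series design calls wild type), Bacillus thuringiensis strain and time. The labels' protocols give exposure on agar at the fourth larval stage, extraction with Trizol, an Illumina TruSeq RNA kit with 1 µg of total RNA, and an Illumina HiSeq instrument. Per the submitters' processing notes the authors used STAR 2.5.3a for alignment. The counting tool, genome build, annotation, strand setting and treatment of reads that map to several places are not given in the sources used here. The values the authors deposited are raw counts per gene, whole numbers with WormBase gene identifiers. Because the handling of shared reads is unknown, members of near-identical families (vitellogenins, pals, ssp and msp genes, small heat shock proteins) are uncertain, and so are overlapping and antisense genes, since strand use is unknown.

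Each count column was assigned to its library through the code that the labels give for it, and 0 columns were left without a library. The table holds 46748 gene identifiers, of which 43693 matched a symbol in the WBcel235 assembly with Ensembl release 115 annotation, and 17938 had no count. Total counts were 14210439 to 24339517 per library. No pair of replicates differed by so little as to be the same library: over genes with a summed count of at least 10, chi-square per degree of freedom between replicates was 1.97 to 59.8. 1 count was worth 0.0704 CPM in the shallowest library.

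Groups, comparisons, tests, gene lists and alternatives were fixed before the data were examined, except where the text says otherwise. Counts were scaled with trimmed mean of M values (TMM) factors, genes with low counts were removed with filterByExpr, leaving 17002 genes (16206 with a symbol) that hold at least 99.9% of each library's counts, and a negative binomial model with 1 mean per group was fitted to all 36 libraries with edgeR 4.0.16 (glmQLFit with robust dispersions, common biological coefficient of variation 0.169) in R 4.3.3. edgeR's quasi-likelihood F test gave p-values that were Benjamini-Hochberg adjusted within each comparison, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the root of F. Levels are CPM on TMM-scaled library sizes, given as mean ± SD. All 23 comparisons came from this 1 model: the libraries labelled elt-2 RNAi against empty vector for each strain and time (6), Bt679 and Bt247 against Bt407 in empty vector (4), Bt247 against Bt679 in empty vector (2), 12 h against 6 h on Bt407 in empty vector (1), the interactions of RNAi with strain against Bt407 (4) and between Bt247 and Bt679 (2), and, added after the data were seen, Bt679 and Bt247 against Bt407 in the libraries labelled elt-2 RNAi (4). Treating Bt407 as the reference follows its use in this field, since the labels give no strain a role.

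For genes whose lower group had 0 counts over its 3 libraries the fold is a lower bound against a floor of 3 counts over the 3 libraries, and for those with 1 to 3 counts the ratio is given with an exact (Clopper-Pearson) 95% interval. Fitted log2 fold changes of such genes, interactions included, depend on the prior count and are no bound. Named genes are elt-2, the 3 highest and 3 lowest log2 fold changes per comparison among called genes with mean log2 CPM of at least 3 and, for 2 groups, non-overlapping library values, up to 4 members per described list (smallest adjusted p, 2 per direction), and nhr-99, nhr-193, jun-1, elt-7, elt-4, pmk-1 and hlh-30.

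A total of 41 gene lists was written beforehand from general knowledge of worm pathways, gene families and tissue markers, neuron, muscle, pharynx and germline markers among them. 40 were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the 40 lists of each comparison, and again with an estimated correlation. Of 760 list tests in the comparisons fixed beforehand camera called 345, and 6 of these held with an estimated correlation. Members were also adjusted over the list alone.

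Alternatives were the median-ratio (RLE) size factors, DESeq2 1.42.0, no low-count filter, the replicate number as a block, a fit on only the libraries compared, and leaving out each library in turn. Tests were checked in simulations with real dispersions and library sizes, equal group means and few changes. Rates here may differ. For RNAi on Bt679 at 6 h, 40%, 60%, 84% and 98% of genes changed by 1.5, 2, 4 and 8-fold were recovered. False calls were 4.73%. For the Bt679 interaction at 6 h recovery was 14%, 46%, 66% and 78%, with 4.67% false. No reads were analysed here.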

Results

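RNA was sequenced from whole bodies of the nematode Caenorhabditis elegans after RNA interference (RNAi) against elt-2, or with an empty vector, and exposure to the spore-forming soil bacterium Bacillus thuringiensis. elt-2 encodes a GATA transcription factor that keeps intestinal genes switched on. Worms at the fourth larval stage were placed on the strains B-18679, B-18247 or B-18407, called Bt679, Bt247 and Bt407 here, mixed 1 to 100, 1 to 10 and 1 to 2 into the food bacterium Escherichia coli OP50. They were collected after 6 h or 12 h. The 36 libraries fall into 12 groups of 3, 1 for each RNAi arm, strain and time. 1 count was worth 0.0704 CPM (counts scaled to a common library total) in the shallowest library. Replicates of a group correlated at r = 0.967 to 0.994 across genes. The labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical, and counting intervals and floors cover counting error only.

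**Figure D1:**
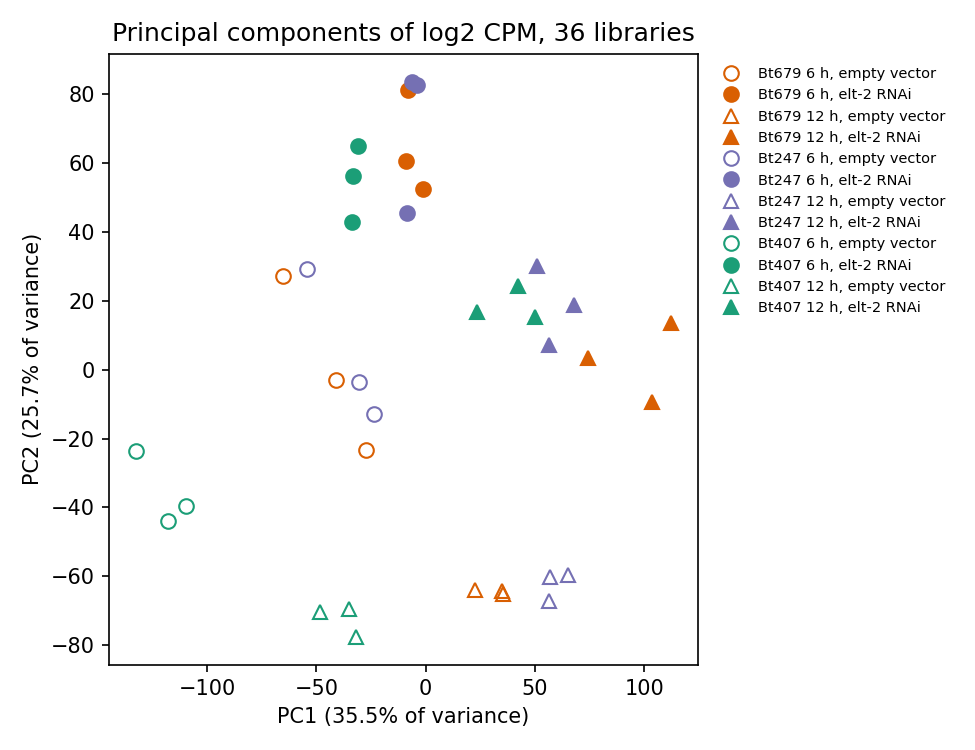
Each point is 1 of the 36 libraries, placed by its first and second principal components of log2 CPM (arbitrary units), which hold 35.5% and 25.7% of the variance, with colour for strain, shape for time and filled symbols for libraries labelled elt-2 RNAi. The 3 empty vector libraries on Bt407 at 6 h lie lowest on the first component, and at 12 h the libraries labelled elt-2 RNAi lie above the empty vector libraries on the second component for every strain.

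elt-2 itself, the target of the RNAi, was measured first as a check of the labels. The gene (WBGene00001250) lies on chromosome X from 10481240 to 10483441 on the plus strand in the WBcel235 assembly with Ensembl release 115 annotation, whose positions are used throughout. On Bt679 its level was 11.9 ± 3.18 CPM (SD, n = 3) in the libraries labelled elt-2 RNAi and 21 ± 1.11 CPM in empty vector at 6 h. The levels were 14.5 ± 2.30 against 22 ± 0.727 CPM at 12 h. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called both falls, with log2 fold changes of -0.82 (SE 0.23, adjusted p = 0.0125) and -0.60 (SE 0.22, adjusted p = 0.0289). On Bt247 the levels were 16 ± 5.24 against 19.2 ± 0.443 CPM at 6 h and 16 ± 1.32 against 22.9 ± 0.689 CPM at 12 h. Neither difference passed the test, at -0.26 (SE 0.22, adjusted p = 0.451) and -0.48 (SE 0.22, adjusted p = 0.108). On Bt407 elt-2 mRNA was not measurably lower. Libraries labelled elt-2 RNAi held 19.8 ± 9.34 CPM at 6 h against 17.9 ± 1.66 CPM in empty vector. RNAi replicates 1 to 3 held 30.4, 12.56 and 16.6 CPM. The 12 h levels were 14 ± 2.01 against 15.5 ± 1.94 CPM. The Bt407 log2 fold changes were 0.15 (SE 0.22, adjusted p = 0.619) and -0.15 (SE 0.22, adjusted p = 0.648). Of the 18 libraries labelled elt-2 RNAi, 13 lay below the lowest empty vector library of their strain and time and 2 lay above the highest. The same label is kept for all 18, and directions on Bt407 and Bt247 rest on libraries in which elt-2 was not called lower.

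**Figure D2:**
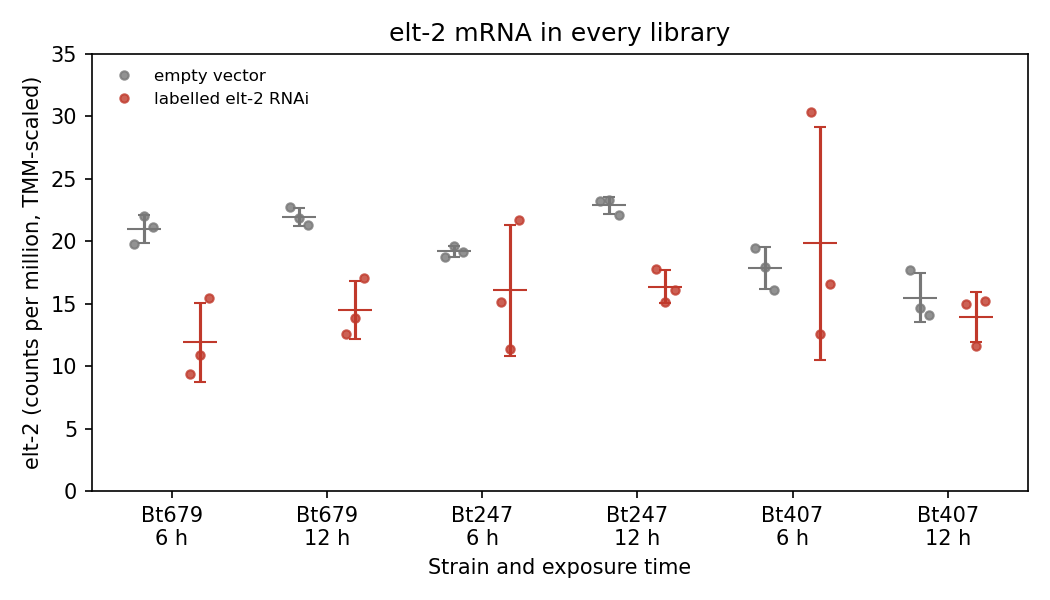
TMM-scaled CPM of elt-2 (vertical axis) by strain and exposure time (horizontal axis), with 1 point per library, the group mean as a horizontal tick and 1 SD as the error bar (n = 3). The empty vector libraries on Bt679 and Bt247 cluster near 20 CPM, while the libraries labelled elt-2 RNAi are lower on Bt679 and scattered on Bt407 at 6 h, where replicate 1 reached 30.4 CPM.

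The first question was how worms of the 2 RNAi arms differed on each strain. On Bt679 at 6 h the libraries labelled elt-2 RNAi held more RNA of the intracellular pathogen response, a set of pals genes and ubiquitin ligase parts known from microsporidian and viral infection. They held less RNA of the effectors that lie downstream of the p38 kinase PMK-1. pals-12 rose with a log2 fold change of 4.43 (SE 0.41) and pals-3 with 3.63 (SE 0.41). The C-type lectin gene clec-67 fell with -5.81 (SE 0.56) and the infection response gene irg-5 with -3.40 (SE 0.35). The cathepsin genes cpz-2 (-4.29) and cpr-6 (-3.23) and the lysozyme genes lys-1 (-3.28) and lys-4 (-3.72) fell, and the neuron markers ida-1 (0.68) and egl-3 (0.68) rose. Among genes with a mean log2 CPM of at least 3, the largest rises were in spp-9, which encodes a saposin-like protein and had 1 count in empty vector (ratio 1290, 95% counting interval 232 to 51200), in F15B9.6 (6.7 (SE 0.56)) and in the degenerin-like channel gene delm-2 (6.56 (SE 0.68)). Replicate 1 labelled elt-2 RNAi stood apart, and without it the log2 fold changes of F15B9.6 and delm-2 were 5.45 and 5.29. The largest falls were in the claudin-like clc-13 (ratio 435, interval 148 to 2110), clc-21 (-6.66 (SE 0.80)) and the lipase gene fil-1 (ratio 79.6, interval 26.9 to 388). Of the intracellular pathogen response list 22 of 40 members were higher, 1 lower and 17 not called (24 and 2 adjusted over the list alone, camera adjusted p = 5.93e-13, adjusted p = 0.322 with an estimated correlation). The list mean was 3.73 log2 CPM in replicate 1 labelled elt-2 RNAi, 2.26 and 2.48 in replicates 2 and 3, and 0.48 to 1.77 in empty vector. Among the p38 pathway targets 0 of 14 members were higher, 9 lower and 5 not called (0 and 10 adjusted over the list alone, camera adjusted p = 9.85e-09, adjusted p = 0.122 with an estimated correlation). For digestive proteases 0 of 22 members were higher, 12 lower and 10 not called (1 and 12 adjusted over the list alone, camera adjusted p = 1.42e-08, adjusted p = 0.298 with an estimated correlation). For lysozymes 0 of 13 members were higher, 4 lower and 9 not called (0 and 6 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.298 with an estimated correlation). The GATA factor genes elt-7 (-0.80 (SE 0.23)) and elt-4 (-1.59 (SE 0.54)) and the nuclear receptor gene nhr-193 (-1.45 (SE 0.27)) also fell. The test called 1493 genes higher and 1389 lower of 17002, and 419 genes in all when it was fitted on these 6 libraries alone.

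At 12 h on Bt679 genes of digestion, yolk and the germline differed between the arms. The aspartyl protease gene asp-1 fell with a log2 fold change of -3.56 (SE 0.19), cpr-6 with -4.21 (SE 0.32). lys-1 (-5.65 (SE 0.34)), clec-85 (-4.37 (SE 0.25)) and the lipase gene lipl-5 (-5.28 (SE 0.34)) fell. The yolk protein genes vit-6 (-3.40 (SE 0.35)) and vit-2 (-4.38 (SE 0.45)) fell, the germ granule gene pgl-3 fell by less (-0.82). The sperm-specific genes ssp-37 (1.52 (SE 0.21)) and ssp-34 (3.47 (SE 0.63)) rose. The intestinal proton pump gene vha-6 (-3.34) and the intestinal actin gene act-5 (-1.51) fell, as did ech-7, an enoyl-CoA hydratase gene (-6.41). The antibacterial peptide genes cnc-4 (1.63) and abf-5 (1.80) rose. Sperm markers gave 51 higher, 0 lower and 3 not called of 54 (51 and 0 adjusted over the list alone, camera adjusted p = 2.08e-15, adjusted p = 0.327 with an estimated correlation). Oocyte and germline markers gave 0 higher, 24 lower and 4 not called of 28 (0 and 24 adjusted over the list alone, camera adjusted p = 1.75e-09, adjusted p = 0.29 with an estimated correlation). All 6 vitellogenin genes tested fell (0 higher, 6 lower, 0 not called, and the same adjusted over the list alone, camera adjusted p = 5.99e-08, adjusted p = 0.0826 with an estimated correlation). The list calls for 4 lists held with an estimated correlation here. Of digestive proteases 0 of 22 members were higher, 20 lower and 2 not called (0 and 20 adjusted over the list alone, camera adjusted p = 1.69e-16, and still adjusted p = 0.0248 with an estimated correlation). For p38 pathway targets 0 of 14 members were higher, 13 lower and 1 not called (0 and 13 adjusted over the list alone, camera adjusted p = 2.01e-14, and still adjusted p = 0.0119 with an estimated correlation). For lysozymes 0 of 13 members were higher, 9 lower and 4 not called (0 and 9 adjusted over the list alone, camera adjusted p = 1.89e-06, and still adjusted p = 0.0248 with an estimated correlation). Among intestinal structure and marker genes 1 of 21 members were higher, 18 lower and 2 not called (1 and 18 adjusted over the list alone, camera adjusted p = 7.29e-07, and still adjusted p = 0.0248 with an estimated correlation). The intracellular pathogen response was mixed: 18 of 40 members were higher, 5 lower and 17 not called (20 and 6 adjusted over the list alone, camera adjusted p = 0.000635, adjusted p = 0.529 with an estimated correlation), with pals-3 (4.22) and pals-12 (3.52) up and pals-39 (-2.01) and pals-18 (-1.07) down. The largest changes were rises in F26F2.4 (ratio 99, interval 33.6 to 483), spp-9 (6.03 (SE 0.67)) and pals-11 (5.66 (SE 0.86)). Those downward were clc-13 (-9.57 (SE 1.05)), clc-21 (-7.26 (SE 0.74)) and fil-1 (-6.78 (SE 0.64)). edgeR called 3813 genes higher and 3861 lower, a total of 7674 that came to 4905 without replicate 1 of the group labelled elt-2 RNAi.

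On Bt247 at 6 h genes of the intracellular pathogen response rose, with pals-12 at a log2 fold change of 5.28 (SE 0.42) and pals-3 at 5.19 (SE 0.44). Vacuolar proton pump genes rose modestly, as in vha-20 (0.65 (SE 0.11)) and vha-19 (0.75 (SE 0.13)), together with the peptide transporter gene pept-1 (1.99 (SE 0.33)). p38 effectors went both ways: clec-67 (-4.22 (SE 0.50)) and irg-5 (-2.65 (SE 0.33)) fell, while K08D8.4 (1.26 (SE 0.35)) and lys-2 (1.49 (SE 0.51)) rose. Of the intracellular pathogen response 32 of 40 members were higher, 0 lower and 8 not called (33 and 0 adjusted over the list alone, camera adjusted p = 2.8e-29, adjusted p = 0.119 with an estimated correlation). Lysosome v-ATPase genes gave 16 higher, 1 lower and 5 not called of 22 (16 and 2 adjusted over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.707 with an estimated correlation). p38 pathway targets gave 2 higher, 8 lower and 4 not called of 14 (2 and 8 adjusted over the list alone, camera adjusted p = 7.87e-05, adjusted p = 0.558 with an estimated correlation). F-box A proteins gave 47 higher, 14 lower and 77 not called of 138 (54 and 16 adjusted over the list alone, camera adjusted p = 8.86e-05, adjusted p = 0.773 with an estimated correlation). For intestinal structure and marker genes 10 of 21 members were higher, 3 lower and 8 not called (10 and 3 adjusted over the list alone, camera adjusted p = 0.0152, adjusted p = 0.707 with an estimated correlation). Largest in size were the rises of spp-9 (9.35 (SE 0.64)), F26F2.4 (8.52 (SE 0.73)) and delm-2 (8.0 (SE 0.71)). Largest downward were clc-13 (ratio 260, interval 46.2 to 10300), the saposin-like spp-20 (-6.02 (SE 0.53)) and C18H7.11 (-4.91 (SE 0.43)). The test called 1825 genes higher and 1232 lower. That total of 3057 fell to 1868 and 2026 without replicates 1 and 2 labelled elt-2 RNAi and to 2008 without empty vector replicate 2.

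At 12 h on Bt247 immune genes again differed, pals-4 rising by 5.88 (SE 0.41) and pals-12 by 6.01 (SE 0.44) on the log2 scale. The p38 effectors clec-67 (-6.18 (SE 0.51)) and C17H12.8 (-6.68 (SE 0.61)) fell. Eggshell and oocyte genes were slightly higher, such as cpg-3 (0.59 (SE 0.08)) and perm-2 (0.68 (SE 0.15)). The endoplasmic reticulum stress genes pek-1 (1.03) and hsp-4 (0.84) and the fatty acid binding protein gene lbp-6 (1.24) also rose. Of the intracellular pathogen response 30 of 40 members were higher, 2 lower and 8 not called (31 and 2 adjusted over the list alone, camera adjusted p = 2.41e-24, adjusted p = 0.121 with an estimated correlation). p38 pathway targets gave 0 higher, 11 lower and 3 not called of 14 (0 and 11 adjusted over the list alone, camera adjusted p = 9.98e-11, and still adjusted p = 0.0498 with an estimated correlation). For oocyte and germline markers 16 of 28 members were higher, 1 lower and 11 not called (17 and 2 adjusted over the list alone, camera adjusted p = 4.5e-05, adjusted p = 0.606 with an estimated correlation). For the ER unfolded protein response 10 of 18 members were higher, 0 lower and 8 not called (11 and 0 adjusted over the list alone, camera adjusted p = 4.5e-05, adjusted p = 0.343 with an estimated correlation). Digestive proteases gave 6 higher, 11 lower and 5 not called of 22 (6 and 11 adjusted over the list alone, camera adjusted p = 0.0152, adjusted p = 0.606 with an estimated correlation). The extremes were delm-2 (8.68 (SE 0.78)), pals-9 (8.56 (SE 0.81)) and spp-9 (8.27 (SE 0.60)) upward. Downward they were clc-13 (0 counts in the group labelled elt-2 RNAi, at least 209-fold lower against a floor of 3 counts over its 3 libraries), clc-21 (-6.79 (SE 0.74)) and sysm-1 (-6.74 (SE 0.67)). There were 2190 genes called higher and 2137 lower, a total of 4327 that became 2838 without empty vector replicate 3.

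On Bt407, where elt-2 was not called lower, the RNAi arms still differed widely at 6 h. The cullin gene cul-6 of the intracellular pathogen response rose with a log2 fold change of 3.23 (SE 0.21, adjusted p = 2e-12) and pals-3 with 7.87 (SE 0.61). Lysozyme genes divided, lys-4 (-6.33 (SE 0.33)) and lys-6 (-6.19 (SE 0.40)) falling and lys-3 (3.24 (SE 0.70)) and ilys-4 (1.79 (SE 0.24)) rising. Among cathepsins cpr-3 rose (5.02) while cpr-6 (-3.75) and cpz-2 (-3.22) fell. Oocyte and sperm markers moved in the directions seen on Bt679 at 12 h, with the oocyte gene oma-1 (-0.78) lower and ssp-34 (2.76) and spe-11 (1.67) higher. The yolk gene vit-6 (-1.36) was lower too. Of the intracellular pathogen response 32 of 40 members were higher, 2 lower and 6 not called (34 and 2 adjusted over the list alone, camera adjusted p = 1.02e-20, adjusted p = 0.21 with an estimated correlation). For digestive proteases 1 of 22 members were higher, 17 lower and 4 not called (1 and 17 adjusted over the list alone, camera adjusted p = 1.27e-08, adjusted p = 0.263 with an estimated correlation). For lysozymes 2 of 13 members were higher, 9 lower and 2 not called (3 and 9 adjusted over the list alone, camera adjusted p = 2.4e-05, adjusted p = 0.207 with an estimated correlation). Oocyte and germline markers gave 0 higher, 25 lower and 3 not called of 28 (0 and 25 adjusted over the list alone, camera adjusted p = 7.59e-09, adjusted p = 0.507 with an estimated correlation). Sperm markers gave 47 higher, 0 lower and 7 not called of 54 (50 and 0 adjusted over the list alone, camera adjusted p = 7.59e-09, adjusted p = 0.598 with an estimated correlation). F-box A proteins gave 65 higher, 10 lower and 63 not called of 138 (65 and 10 adjusted over the list alone, camera adjusted p = 1.22e-05, adjusted p = 0.507 with an estimated correlation). For p38 pathway targets 2 of 14 members were higher, 9 lower and 3 not called (4 and 9 adjusted over the list alone, camera adjusted p = 0.00389, adjusted p = 0.507 with an estimated correlation). The largest rises were in delm-2 (0 counts in empty vector, at least 351-fold higher), pals-9 (ratio 668, interval 228 to 3240) and T19C9.8 (9.0 (SE 0.74)). The largest falls were in lys-4, in the metallothionein gene mtl-2 (-5.34 (SE 0.38)) and in spp-4 (-5.17 (SE 0.27)). Totals were 3664 genes higher and 3602 lower, against 3268 and 4386 with median-ratio (RLE) size factors and 3218 and 4419 with DESeq2.

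At 12 h on Bt407 several of the same genes differed. cul-6 (3.28 (SE 0.21)) and pals-27 (5.54 (SE 0.37)) were higher. The lysozyme genes lys-4 (-8.09 (SE 0.36)), lys-6 (-6.12 (SE 0.36)) and lys-7 (-5.16 (SE 0.40)) were lower, and mtl-1 (-5.33 (SE 0.49)) and mtl-2 (-7.12 (SE 0.42)), which bind metals, fell too. The AP-1 genes fos-1 (1.49) and jun-1 (1.09) and the kinase phosphatase gene vhp-1 (1.56) rose, as did the neuronal genes egl-3 (1.21) and unc-64 (1.31). Of the intracellular pathogen response 32 of 40 members were higher, 0 lower and 8 not called (34 and 0 adjusted over the list alone, camera adjusted p = 1.38e-21, adjusted p = 0.122 with an estimated correlation). Lysozymes gave 2 higher, 9 lower and 2 not called of 13 (2 and 9 adjusted over the list alone, camera adjusted p = 9.39e-09, and still adjusted p = 0.0168 with an estimated correlation). Digestive proteases gave 1 higher, 16 lower and 5 not called of 22 (1 and 17 adjusted over the list alone, camera adjusted p = 4.69e-11, adjusted p = 0.122 with an estimated correlation). Proteasome subunits, among them pbs-4 (-0.50), gave 0 higher, 30 lower and 3 not called of 33 (0 and 31 adjusted over the list alone, camera adjusted p = 2.45e-10, adjusted p = 0.418 with an estimated correlation). For neuron markers 12 of 24 members were higher, 0 lower and 12 not called (12 and 0 adjusted over the list alone, camera adjusted p = 2.93e-05, adjusted p = 0.25 with an estimated correlation). The largest rises were in F57G4.11 (0 counts in empty vector, at least 325-fold higher), F26F2.4 (ratio 1660, interval 297 to 65400) and pals-9 (ratio 1270, interval 352 to 10500). Falls were largest in lys-4, mtl-2 and ech-7 (-6.89 (SE 0.39)). edgeR called 3183 genes higher and 2916 lower.

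Some of the RNAi difference was common to the strains. At 6 h 710 genes were higher and 367 lower on all 3 strains, where independent lists would give 34.5 and 21.3. At 12 h the numbers were 382 and 513 against 91.9 and 83.2. nhr-193, a nuclear receptor gene, was lower in all 6 comparisons, from -2.40 (SE 0.26) on Bt407 at 6 h to -0.87 (SE 0.26) on Bt247 at 6 h, and cul-6 was higher in all 6. Correlations of the log2 fold changes across genes, which are not independent replicates, lay between 0.632 and 0.771 at 6 h and between 0.435 and 0.616 at 12 h, the lowest being Bt679 with Bt247. Among genes called on at least 2 strains, 250 went in opposite directions at 6 h and 1433 at 12 h. These comparisons share no libraries. The p38 kinase gene pmk-1 itself passed the test only on Bt407 at 12 h (0.25 (SE 0.09)).

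**Figure D3:**
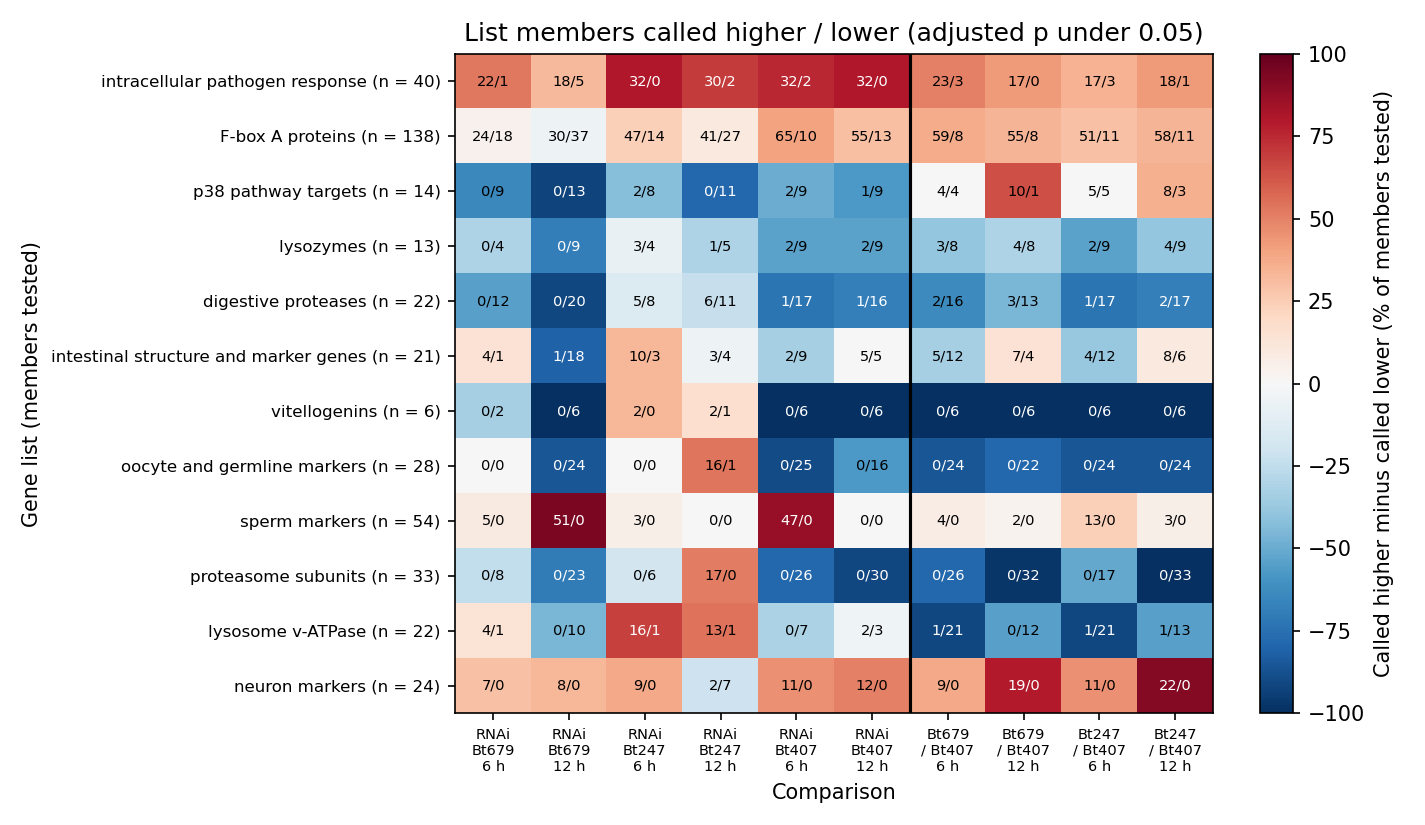
For 12 gene lists (vertical axis, with the number of members tested) and 10 comparisons (horizontal axis), each cell gives the number of members called higher and lower, and its colour the difference of these counts as a percentage of members tested. The 6 columns at the left compare the libraries labelled elt-2 RNAi with empty vector, where the intracellular pathogen response ran from 18 higher and 5 lower (Bt679, 12 h) to 32 and 0 (Bt247, 6 h, and Bt407, 12 h), and the 4 at the right compare strains with Bt407 in empty vector, where all 6 vitellogenins were lower in each.

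The next question was how worms with an empty vector responded to Bt679 and Bt247, with Bt407, a strain used as a non-pathogenic control in this field, as the reference. Strain and dilution changed together and could not be separated. TMM factors of the 6 empty vector Bt407 libraries were 0.782 to 0.961 and those of the other 30 libraries 0.947 to 1.17. Each comparison with Bt407 rests on those references. On Bt679 at 6 h yolk, oocyte and lysosomal pump genes were lower: vit-6 had a log2 fold change of -2.82 (SE 0.34), the oocyte regulator oma-2 -1.0 (SE 0.12) and the proton pump genes vha-11 -1.3 (SE 0.09) and vha-13 -1.23 (SE 0.11). Immune genes divided, with lys-3 (7.25 (SE 0.69)), cul-6 (2.64 (SE 0.20)), pals-39 (5.94 (SE 0.59)) and the antimicrobial peptide genes cnc-4 (1.82 (SE 0.27)) and nlp-31 (1.59 (SE 0.24)) higher. Lower were lys-4 (-6.11 (SE 0.32)) and lys-6 (-5.98 (SE 0.39)). The kinase gene kgb-2 (2.63), the kinase phosphatase gene vhp-1 (1.33) and jun-1 (1.28) rose. For oocyte and germline markers 0 of 28 members were higher, 24 lower and 4 not called (0 and 24 adjusted over the list alone, camera adjusted p = 2.05e-12, adjusted p = 0.291 with an estimated correlation). Lysosome v-ATPase genes gave 1 higher, 21 lower and 0 not called of 22 (1 and 21 adjusted over the list alone, camera adjusted p = 2.05e-12, adjusted p = 0.226 with an estimated correlation). Digestive proteases gave 2 higher, 16 lower and 4 not called of 22 (3 and 16 adjusted over the list alone, camera adjusted p = 1.7e-07, adjusted p = 0.291 with an estimated correlation). Vitellogenins gave 0 higher, 6 lower and 0 not called of 6 (0 and 6 adjusted over the list alone, camera adjusted p = 1.33e-05, adjusted p = 0.291 with an estimated correlation). For the intracellular pathogen response 23 of 40 members were higher, 3 lower and 14 not called (23 and 3 adjusted over the list alone, camera adjusted p = 4.01e-06, adjusted p = 0.376 with an estimated correlation). p38 and JNK pathway components gave 9 higher, 3 lower and 5 not called of 17 (10 and 3 adjusted over the list alone, camera adjusted p = 0.00847, adjusted p = 0.291 with an estimated correlation). The largest changes were clc-13 (ratio 1150, interval 205 to 45300), nhr-247 (ratio 569, interval 157 to 4700) and F33H12.7 (8.76 (SE 0.68)) upward. Downward they were Y39B6A.1 (-7.62 (SE 0.51)), F46F2.3 (-7.30 (SE 0.70)) and vit-1 (-6.78 (SE 0.78)). The test called 3435 genes higher and 3585 lower (2996 and 4234 with RLE size factors, 2995 and 4272 with DESeq2, 3057 and 2482 without Bt407 replicate 3).

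At 12 h on Bt679 p38 effectors were higher, K08D8.4 with a log2 fold change of 3.99 (SE 0.39) and the mucin-like mul-1 with 3.35 (SE 0.41). The infection response gene irg-1, which is not among the p38 pathway targets, rose by 2.77 (SE 0.28). The kinase gene pmk-3 (1.0 (SE 0.08)), fos-1 (1.22 (SE 0.11)), jun-1 (1.38 (SE 0.14)) and, by less, pmk-1 (0.45 (SE 0.09)) and the lysosomal regulator hlh-30 (0.42 (SE 0.16)) rose. Lysozymes stayed divided, lys-3 (5.64) and lys-1 (2.33) up and lys-4 (-6.27) and lys-6 (-6.85) down. Proteasome genes such as rpn-9 (-0.55) and the chondroitin gene cpg-3 (-0.70) of the eggshell were lower and the synaptic gene unc-64 (1.19) was higher. p38 pathway targets gave 10 higher, 1 lower and 3 not called of 14 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000738, adjusted p = 0.394 with an estimated correlation). p38 and JNK pathway components gave 11 higher, 0 lower and 6 not called of 17 (11 and 0 adjusted over the list alone, camera adjusted p = 6.74e-05, adjusted p = 0.19 with an estimated correlation). For proteasome subunits 0 of 33 members were higher, 32 lower and 1 not called (0 and 32 adjusted over the list alone, camera adjusted p = 4.89e-14, adjusted p = 0.334 with an estimated correlation). For neuron markers 19 of 24 members were higher, 0 lower and 5 not called (19 and 0 adjusted over the list alone, camera adjusted p = 1.16e-05, adjusted p = 0.331 with an estimated correlation). Oocyte and germline markers gave 0 higher, 22 lower and 6 not called of 28 (0 and 22 adjusted over the list alone, camera adjusted p = 5.99e-10, adjusted p = 0.394 with an estimated correlation). Lysozymes gave 4 higher, 8 lower and 1 not called of 13 (4 and 8 adjusted over the list alone, camera adjusted p = 0.000153, adjusted p = 0.195 with an estimated correlation). The largest rises were in clc-13 (7.79 (SE 0.92)), nhr-247 (7.66 (SE 0.75)) and C54C8.12 (7.37 (SE 0.97)). Falls were largest in lys-4, the thaumatin-like thn-2 (-6.17 (SE 0.81)) and pud-3 (-6.01 (SE 0.59)). edgeR called 3997 genes higher and 3071 lower.

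Bt247 at 6 h gave falls of vit-6 (-3.70 (SE 0.35) on the log2 scale), asp-1 (-2.99 (SE 0.19)), asp-12 (-5.89 (SE 0.42)) and vha-11 (-1.26 (SE 0.09)) and of the metal-responsive genes mtl-2 (-6.31 (SE 0.40)) and cdr-1 (-5.55 (SE 0.37)). lys-3 (6.96 (SE 0.69)), cpr-3 (4.53 (SE 0.49)), cul-6 (2.47 (SE 0.20)) and cnc-4 (2.12 (SE 0.27)) rose. The nuclear receptor genes nhr-99 (-2.43 (SE 0.31)) and nhr-193 (-1.46 (SE 0.23)) fell. Digestive proteases gave 1 higher, 17 lower and 4 not called of 22 (1 and 18 adjusted over the list alone, camera adjusted p = 2.58e-10, adjusted p = 0.145 with an estimated correlation). Lysosome v-ATPase genes gave 1 higher, 21 lower and 0 not called of 22 (1 and 21 adjusted over the list alone, camera adjusted p = 6.29e-12, adjusted p = 0.145 with an estimated correlation). For oocyte and germline markers 0 of 28 members were higher, 24 lower and 4 not called (0 and 26 adjusted over the list alone, camera adjusted p = 5.56e-12, adjusted p = 0.3 with an estimated correlation). For lysozymes 2 of 13 members were higher, 9 lower and 2 not called (2 and 9 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.145 with an estimated correlation). For vitellogenins 0 of 6 members were higher, 6 lower and 0 not called (0 and 6 adjusted over the list alone, camera adjusted p = 2.64e-06, adjusted p = 0.239 with an estimated correlation). The largest changes were spp-20 (8.41 (SE 0.67)), C54C8.12 (8.28 (SE 1.08)) and F33H12.7 (8.19 (SE 0.68)) upward. Downward they were Y39B6A.1 (-7.76 (SE 0.51)), F46F2.3 (-7.38 (SE 0.69)) and vit-1 (-7.20 (SE 0.80)). There were 3874 genes called higher and 3941 lower (3345 and 4506 with RLE size factors, 3339 and 4582 with DESeq2, 3437 and 2797 without Bt407 replicate 3).

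Bt247 at 12 h gave the highest count of these comparisons, 5662 genes higher and 3775 lower. Yolk genes fell, vit-3 with a log2 fold change of -7.30 (SE 0.59) and vit-4 with -6.10 (SE 0.61), and all 33 proteasome subunits tested were lower, rpn-9 by -0.76 (SE 0.07). The dense-core vesicle gene ida-1 (1.18 (SE 0.10)) and the neuropeptide processing gene egl-3 (1.06 (SE 0.10)) were higher. irg-1 rose by 3.32 and dod-22 by 3.05, as did the nuclear receptor genes nhr-112 (4.1) and nhr-203 (2.71) and hlh-30 (0.63) and fos-1 (1.07). For proteasome subunits 0 of 33 members were higher, 33 lower and 0 not called (0 and 33 adjusted over the list alone, camera adjusted p = 2.48e-17, adjusted p = 0.27 with an estimated correlation). Neuron markers gave 22 higher, 0 lower and 2 not called of 24 (22 and 0 adjusted over the list alone, camera adjusted p = 4.33e-07, adjusted p = 0.27 with an estimated correlation). Pharynx markers gave 15 higher, 0 lower and 5 not called of 20 (17 and 0 adjusted over the list alone, camera adjusted p = 0.00227, adjusted p = 0.431 with an estimated correlation). Nuclear hormone receptors gave 107 higher, 24 lower and 82 not called of 213 (109 and 24 adjusted over the list alone, camera adjusted p = 0.00336, adjusted p = 0.431 with an estimated correlation). Of oocyte and germline markers 0 of 28 members were higher, 24 lower and 4 not called (1 and 24 adjusted over the list alone, camera adjusted p = 2.28e-12, adjusted p = 0.361 with an estimated correlation). For vitellogenins 0 of 6 members were higher, 6 lower and 0 not called (0 and 6 adjusted over the list alone, camera adjusted p = 4.84e-06, adjusted p = 0.279 with an estimated correlation). The largest changes were C54C8.12 (7.11 (SE 0.97)), Y60C6A.1 (7.10 (SE 0.52)) and C49G7.12 (6.07 (SE 0.39)) upward. Downward they were spp-4 (-7.61 (SE 0.32)), vit-3 and lys-4 (-7.18 (SE 0.34)). elt-2 itself was higher on Bt247 than on Bt407 in empty vector at this time (0.57 (SE 0.22)).

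Most genes that Bt679 changed in empty vector Bt247 changed too. At 6 h 2923 genes were higher and 3331 lower on both strains and 0 went in opposite directions, where independent lists would give 783 and 831. Shared genes made up 89.1% of the Bt679 calls and 80% of the Bt247 calls. Across genes the 2 sets of log2 fold changes correlated at 0.931 with a covariance of 1.19. The values were 0.519 and 0.054 in 20 simulations of unchanged groups sharing a control. A separate one called 0 genes in both. At 12 h 3565 genes were higher, 2897 lower and 4 opposite (1330 and 682 from independent lists). This came with a correlation of 0.872 and a covariance of 0.879 against simulated values of 0.537 and 0.029. The 3 control libraries cannot be divided into parts of at least 2, so part of the excess over independent lists may come from the shared controls.

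Set directly against each other in empty vector, Bt247 and Bt679 differed in 3 genes at 6 h, all lower on Bt247. T26H5.9 had a log2 fold change of -1.50 (SE 0.26, adjusted p = 0.0259). The other 2, chosen after their values were seen, were the nuclear receptor gene nhr-246 (-1.66 (SE 0.28)) and WBGene00011149 (-4.94, SE 0.84). At an unadjusted p under 0.05 there were 795 genes, and DESeq2 called 35, of which 4 were higher. The count went to 0 without Bt679 replicate 3 or any of the Bt247 replicates and to 125 without Bt679 replicate 1. The same test fitted on these 6 libraries alone called 0. Digestive proteases were lower as a list with no member passing over all genes: 0 of 22 members were higher, 0 lower and 22 not called (0 and 4 adjusted over the list alone, camera adjusted p = 2.44e-10, adjusted p = 0.37 with an estimated correlation). The intracellular pathogen response gave 0 higher, 0 lower and 40 not called of 40 (0 and 1 adjusted over the list alone, camera adjusted p = 3.94e-08, adjusted p = 0.539 with an estimated correlation). At 12 h the yolk gene vit-3 (-3.95 (SE 0.52)), the aspartyl protease gene asp-12 (-3.31 (SE 0.38)) and the saposin-like spp-4 (-3.17 (SE 0.32)) were lower on Bt247, with lys-7 (-1.41 (SE 0.35)), K08D8.4 (-2.11 (SE 0.35)), nhr-247 (-3.73 (SE 0.54)) and hsp-4 (-0.83 (SE 0.13)). The lectin genes clec-4 (1.83 (SE 0.47)) and clec-186 (1.83 (SE 0.40)), T01D3.6 (1.76 (SE 0.25)) and the pharyngeal gland gene phat-6 (0.94) were higher. For the ER unfolded protein response 0 of 18 members were higher, 4 lower and 14 not called (0 and 10 adjusted over the list alone, camera adjusted p = 5.89e-10, adjusted p = 0.114 with an estimated correlation). Vitellogenins gave 0 higher, 2 lower and 4 not called of 6 (0 and 6 adjusted over the list alone, camera adjusted p = 1.09e-07, adjusted p = 0.158 with an estimated correlation). Sperm markers gave 0 higher, 0 lower and 54 not called of 54 (0 and 0 adjusted over the list alone, camera adjusted p = 2.27e-12, adjusted p = 0.339 with an estimated correlation). The test called 75 genes higher and 316 lower at 12 h. That count of 391 was 111 without Bt247 replicate 3, 229 without Bt247 replicate 1, 207 and 206 without Bt679 replicates 1 and 2, and 25 higher and 168 lower without Bt679 replicate 3. A fit on these 6 libraries alone called 3918, of which 1999 were higher and 1919 lower, and DESeq2 676.

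Whether the response to a strain differed between the RNAi arms was tested as an interaction. A positive log2 value means a change from Bt407 that was more positive in the libraries labelled elt-2 RNAi. It rests equally on the Bt407 libraries, in which elt-2 was not called lower. For Bt679 at 6 h the intracellular pathogen response to the strain was smaller in those libraries, with interaction values of -2.25 (SE 0.27) for cul-6 and -6.12 (SE 0.72) for pals-39. The F-box gene fbxa-150 (-1.55 (SE 0.22)), dod-19 (-3.22 (SE 0.36)) and lys-3 (-4.45 (SE 0.85)) also had negative values. In contrast lys-6 (5.33 (SE 0.98)), the gut esterase gene ges-1 (1.45 (SE 0.28)) and oma-2 (0.70 (SE 0.17)) had positive ones. For the intracellular pathogen response 1 of 40 members were higher, 23 lower and 16 not called (2 and 27 adjusted over the list alone, camera adjusted p = 6.25e-13, adjusted p = 0.434 with an estimated correlation). Oocyte and germline markers gave 14 higher, 0 lower and 14 not called of 28 (19 and 0 adjusted over the list alone, camera adjusted p = 9.25e-11, adjusted p = 0.441 with an estimated correlation). F-box A proteins gave 0 higher, 28 lower and 110 not called of 138 (1 and 36 adjusted over the list alone, camera adjusted p = 4.58e-08, adjusted p = 0.441 with an estimated correlation). edgeR called 857 interactions positive and 1093 negative, against 1826 and 892 with RLE size factors, which moved the median of all genes by 0.107. DESeq2 gave 2159 and 1019. The total of 1950 was 895 and 1286 without Bt407 replicates 1 and 2 labelled elt-2 RNAi, 1145 without empty vector Bt407 replicate 3, 1083 without Bt679 replicate 2 labelled elt-2 RNAi, and 1216 and 1054 without empty vector Bt679 replicates 2 and 3.

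For Bt679 at 12 h these genes had negative interaction values: pals-39 -7.60 (SE 0.67), pals-37 -7.24 (SE 0.68), K08D8.4 -4.17 (SE 0.51), lys-2 -4.48 (SE 0.76), dod-19 -4.86 (SE 0.36) and the kinase gene kgb-2 -3.05 (SE 0.40). Yolk gene vit-6 (-2.55 (SE 0.46)), the chaperone gene crt-1 (-0.83 (SE 0.11)) and the AP-1 gene jun-1 (-0.81 (SE 0.19)) were also negative. lys-4 (4.41 (SE 0.70)), mtl-1 (5.45 (SE 0.65)), thn-1 (5.12 (SE 1.08)) and gst-33 (4.67 (SE 0.43)) were positive. For the intracellular pathogen response 0 of 40 members were higher, 26 lower and 14 not called (0 and 28 adjusted over the list alone, camera adjusted p = 1.33e-16, adjusted p = 0.135 with an estimated correlation). CUB-like and downstream-of-DAF-16 genes gave 0 higher, 14 lower and 17 not called of 31 (0 and 16 adjusted over the list alone, camera adjusted p = 2.3e-07, adjusted p = 0.126 with an estimated correlation). p38 pathway targets gave 0 higher, 9 lower and 5 not called of 14 (0 and 12 adjusted over the list alone, camera adjusted p = 2.8e-07, adjusted p = 0.126 with an estimated correlation). The ER unfolded protein response gave 0 higher, 11 lower and 7 not called of 18 (0 and 13 adjusted over the list alone, camera adjusted p = 9.57e-07, adjusted p = 0.129 with an estimated correlation). For sperm markers, as in ssp-37 (1.05), 13 of 54 members were higher, 0 lower and 41 not called (43 and 0 adjusted over the list alone, camera adjusted p = 1.08e-09, adjusted p = 0.547 with an estimated correlation). The test called 1279 positive and 2190 negative. The total of 3469 was 5308 without Bt679 replicate 2 labelled elt-2 RNAi and 2277 in a fit on the 12 libraries alone.

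For Bt247 at 6 h the falls of intestinal and oocyte genes were smaller in the libraries labelled elt-2 RNAi. Interaction values were 1.74 (SE 0.22) for asp-6, 3.77 (SE 0.50) for asp-12, 0.84 (SE 0.13) for vha-11, 2.01 (SE 0.28) for ges-1. They were 2.18 (SE 0.32) for the sodium-proton exchanger gene nhx-2, 2.41 (SE 0.45) for vit-6 and 0.82 (SE 0.17) for the germline gene mex-5. lys-6 (5.84 (SE 0.95)), spp-2 (4.91 (SE 0.75)) and nhr-99 (1.79 (SE 0.43)) were positive, and lys-3 (-5.48 (SE 0.85)), cpr-3 (-3.92 (SE 0.62)) and cul-6 (-2.02 (SE 0.27)) negative. Lysosome v-ATPase genes gave 12 higher, 1 lower and 9 not called of 22 (16 and 1 adjusted over the list alone, camera adjusted p = 1e-08, adjusted p = 0.231 with an estimated correlation). Digestive proteases gave 11 higher, 1 lower and 10 not called of 22 (11 and 1 adjusted over the list alone, camera adjusted p = 9.43e-07, adjusted p = 0.242 with an estimated correlation). Intestinal structure and marker genes gave 9 higher, 1 lower and 11 not called of 21 (12 and 2 adjusted over the list alone, camera adjusted p = 9.66e-06, adjusted p = 0.128 with an estimated correlation). For oocyte and germline markers 18 of 28 members were higher, 0 lower and 10 not called (21 and 0 adjusted over the list alone, camera adjusted p = 3.75e-10, adjusted p = 0.39 with an estimated correlation). There were 1192 positive and 1071 negative calls, against 1982 and 892 with RLE size factors and 2318 and 974 with DESeq2. The total of 2263 was 1289 without Bt407 replicate 1 labelled elt-2 RNAi and 3441 in a fit on the 12 libraries alone.

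For Bt247 at 12 h 2228 interactions were positive and 2568 negative, a balance that turned to 2649 and 2234 with RLE size factors and 2777 and 2346 with DESeq2. Proteasome genes, lower on Bt247 in empty vector, had positive values, as in rpn-9 (0.69 (SE 0.10)) and pas-7 (0.71 (SE 0.11)). So did vit-3 (5.30 (SE 0.68)), spp-4 (6.74 (SE 0.51)), lys-7 (3.95 (SE 0.53)), asp-8 (4.52 (SE 0.56)) and the eggshell gene cpg-3 (1.06 (SE 0.11)). lys-3 (-4.53 (SE 0.76)), nhr-112 (-3.92 (SE 0.35)), ida-1 (-1.17 (SE 0.14)), jun-1 (-0.85 (SE 0.19)) and hlh-30 (-0.70 (SE 0.22)) were negative. For proteasome subunits 30 of 33 members were higher, 0 lower and 3 not called (31 and 0 adjusted over the list alone, camera adjusted p = 7.09e-18, adjusted p = 0.352 with an estimated correlation). Oocyte and germline markers gave 20 higher, 1 lower and 7 not called of 28 (23 and 1 adjusted over the list alone, camera adjusted p = 4e-10, adjusted p = 0.43 with an estimated correlation). Neuron markers gave 0 higher, 13 lower and 11 not called of 24 (0 and 18 adjusted over the list alone, camera adjusted p = 3.53e-06, adjusted p = 0.352 with an estimated correlation).

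The last interaction asked whether the RNAi difference itself was unlike on the 2 strains, a positive value meaning a more positive difference on Bt247. At 6 h few genes passed: T26H5.9 (2.04 (SE 0.39)), ZC204.12 (1.99 (SE 0.36)), the lectin gene clec-62 (1.78 (SE 0.34)) and asp-1 (1.22 (SE 0.25)) were more positive on Bt247 and dpsm-1 (-1.67 (SE 0.35)) less. Of the intracellular pathogen response 0 of 40 members were higher, 0 lower and 40 not called (14 and 0 adjusted over the list alone, camera adjusted p = 1.51e-14, adjusted p = 0.336 with an estimated correlation), with pals-33 at 2.21 not passing over all genes (0.114 adjusted). Digestive proteases gave 1 higher, 0 lower and 21 not called of 22 (8 and 0 adjusted over the list alone, camera adjusted p = 3.37e-10, adjusted p = 0.267 with an estimated correlation). edgeR called 22 positive and 2 negative at 6 h. That total of 24 was 1103 without Bt679 replicate 1 labelled elt-2 RNAi, 161 without empty vector Bt679 replicate 1 and 0 or 1 without each of the other 10 libraries in turn. It was 11 with RLE size factors, 0 with no low-count filter, 0 in a fit on the 12 libraries alone and 187 (151 positive and 36 negative) with DESeq2. At 12 h the strains parted in yolk, germline and immune genes. vit-3 (7.67 (SE 0.73)), vit-4 (6.80 (SE 0.79)), asp-12 (5.43 (SE 0.52)), hsp-4 (1.87 (SE 0.19)), lipl-5 (3.39 (SE 0.42)), pals-39 (4.19 (SE 0.58)) and cpg-3 (1.09 (SE 0.11)) were more positive on Bt247. The sperm-specific ssp-35 (-2.89 (SE 0.67)) and ssp-37 (-1.38 (SE 0.29)) and the ribosomal rpl-24.2 (-0.85 (SE 0.16)) were less so. For oocyte and germline markers 22 of 28 members were higher, 0 lower and 6 not called (23 and 0 adjusted over the list alone, camera adjusted p = 1.64e-13, adjusted p = 0.187 with an estimated correlation). For sperm markers 0 of 54 members were higher, 46 lower and 8 not called (0 and 50 adjusted over the list alone, camera adjusted p = 4.56e-11, adjusted p = 0.332 with an estimated correlation). Vitellogenins gave 6 higher, 0 lower and 0 not called of 6 (6 and 0 adjusted over the list alone, camera adjusted p = 1.87e-08, adjusted p = 0.179 with an estimated correlation). The intracellular pathogen response gave 22 higher, 0 lower and 18 not called of 40 (24 and 1 adjusted over the list alone, camera adjusted p = 3.87e-09, adjusted p = 0.235 with an estimated correlation). Digestive proteases gave 14 higher, 0 lower and 8 not called of 22 (15 and 0 adjusted over the list alone, camera adjusted p = 1.87e-08, adjusted p = 0.179 with an estimated correlation). The test called 3120 positive and 2960 negative at 12 h.

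Time alone was compared on Bt407 in empty vector, 12 h against 6 h. The pharyngeal genes abu-11 (4.62 (SE 0.61)) and phat-1 (5.72 (SE 0.76)) and the collagen genes col-65 (7.48 (SE 0.88)) and col-89 (3.26 (SE 0.39)) rose. The collagen genes col-129 (-3.35 (SE 0.41)), col-139 (-3.06 (SE 0.36)) and col-8 (-2.03 (SE 0.24)) fell. The synaptic genes rab-3 (1.38) and unc-17 (1.23) and the lysozyme gene ilys-3 (3.21) rose, and the haem-responsive gene hrg-2 (-3.09) fell. Pharynx markers gave 11 higher, 0 lower and 9 not called of 20 (12 and 0 adjusted over the list alone, camera adjusted p = 8.75e-07, adjusted p = 0.262 with an estimated correlation). Neuron markers gave 12 higher, 0 lower and 12 not called of 24 (17 and 0 adjusted over the list alone, camera adjusted p = 9.4e-07, adjusted p = 0.262 with an estimated correlation). Cuticle collagens gave 51 higher, 34 lower and 51 not called of 136 (52 and 34 adjusted over the list alone, camera adjusted p = 0.0406, adjusted p = 0.763 with an estimated correlation). The largest rises were in K01D12.9 (ratio 636, interval 217 to 3090), T25E4.1 (ratio 650, interval 116 to 25700) and Y47D7A.13 (8.02 (SE 0.98)). edgeR called 1881 genes higher and 1566 lower. The total of 3447 was 1689 without 12 h replicate 3 (1278 higher and 411 lower), 1922 without 6 h replicate 3 (1305 and 617) and 1320 in a fit on these 6 libraries alone (1083 and 237).

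Positions of several genes named repeatedly are chromosome X from 11487784 to 11488203 for spp-9 (WBGene00004994), chromosome V from 17014408 to 17015326 for clc-13 (WBGene00009907). They are chromosome IV from 11621429 to 11623174 for lys-4 (WBGene00003093) and chromosome X from 3567355 to 3572549 for vit-3 (WBGene00006927), all annotated as protein-coding. vit-3 shares most of its sequence with vit-4 and vit-5, and many pals and ssp genes have close copies, so counts of single members of these families are uncertain.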

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

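Of the tests in this part, the one on pals gene copies, those on elt-2 mRNA on Bt407, the one on scaling for the third pattern and the splits were chosen only after the result was seen. Each result here stands out because a tested interaction differed between groups. For the response to Bt679 at 6 h 1950 genes differed between the RNAi arms, among them Y39B6A.1 (5.78), cpr-1 (4.52), Y65B4BR.1 (4.41), clc-21 (-7.94), F33H12.7 (-7.89) and B0348.2 (-7.01). elt-2 itself passed too (-0.97 (SE 0.32, adjusted p = 0.0453) in edgeR), a call lost without Bt407 replicate 1 (-0.53) or Bt679 replicate 1 or 2 labelled elt-2 RNAi, without each empty vector library except Bt679 replicate 1, with RLE size factors, with no low-count filter and with only the libraries compared. The count of 1950 was 895 to 2205 with 1 library left out. At 12 h 3469 genes differed, with mtl-1 (5.45), thn-1 (5.12), lys-4 (4.41), pals-39 (-7.60), T19C9.8 (-7.56), jun-1 (-0.81) and F57G4.11 (-7.70, with 0 counts in a group, so that its value is no bound). The count was 5308 without Bt679 replicate 2 labelled elt-2 RNAi.

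For the response to Bt247 at 6 h 2263 genes differed (1289 without Bt407 replicate 1 labelled elt-2 RNAi), with Y39B6A.1 (6.97), spp-2 (4.91), F09C8.1 (4.86), F33H12.7 (-7.35), spp-20 (-6.14), clc-21 (-5.99), nhr-99 (1.79), nhr-193 (1.53) and jun-1 (-0.70). At 12 h 4796 differed, with spp-4 (6.74), vit-3 (5.30), spp-2 (4.94), C54C8.12 (-7.22), Y60C6A.1 (-6.39), F14F9.3 (-5.89), nhr-99 (1.44), jun-1 (-0.85) and hlh-30 (-0.70).

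The RNAi difference on Bt247 set against that on Bt679 gave 24 genes at 6 h (0 to 1103 with 1 library left out), with T26H5.9 (2.04), ZC204.12 (1.99), clec-62 (1.78) and dpsm-1 (-1.67). At 12 h it gave 6080, with vit-3 (7.67), vit-4 (6.80), math-14 (5.97), F43C1.7 (-4.91), parg-2 (-4.65), cng-1 (-4.45) and nhr-99 (1.33). Strain labels were also redrawn within each RNAi arm after the strain and RNAi differences were taken out, with limma's moderated test on log2 CPM and 100 splits, the real one included. For the responses to Bt679 the real labels called 1134 genes at 6 h (0 in the highest other) and 2161 at 12 h (1), and for those to Bt247 3054 (1) and 5334 (1). In each case 1 of the 100 splits was as large, a share under 0.05. Redrawn labels mix groups that hold the interaction, which can lower their counts. Culture differences that follow the labels are not excluded. For the Bt247 and Bt679 interaction 1 of 100 was as large at 12 h (6647 genes, 4946 in the highest other). At 6 h the real labels called 0 and 100 of 100 were as large. There the highest other called 2624 with Bt679 replicate 1 and Bt247 replicates 1 and 2 set against the rest in both arms. That split is the strain split with Bt679 replicate 1 and Bt247 replicate 3 exchanged in each arm. It points to a structure that the strain labels do not follow, and an exchange of labels was not tested.

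A first pattern is that the intracellular pathogen response list was called higher in the libraries labelled elt-2 RNAi in all 6 comparisons, although its members were mixed on Bt679 at 12 h (18 of 40 higher, 5 lower) and no call held with an estimated correlation (adjusted p = 0.119 to 0.529). Other genes cannot test for reads shared among pals copies. Outside that family cul-6 was higher in 6 comparisons, skr-3 and skr-4 in 4, skr-5 in 1 and chil-27 in 0. RLE size factors moved the median of all genes by at most 0.069 (lowest list median 0.67), but may share errors with TMM. Another infection in the cultures labelled elt-2 RNAi cannot be told apart from the RNAi, since 18 of the 18 libraries had a list mean above every empty vector library of their strain and time. The RNAi as a cause was not tested and stays open beside infection, shared reads and scaling.

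The second is that elt-2 mRNA was not measurably lower on Bt407 in the libraries labelled elt-2 RNAi. Exchanged labels on Bt407 are argued against: of the genes called the same way on Bt679 and Bt247, 89.8% of 1514 at 6 h and 84.5% of 1361 at 12 h moved that way on Bt407 too. A fall as on Bt679 hidden by too few reads cannot be told apart: the lower 95% limits on Bt407 were -0.286 at 6 h and -0.584 at 12 h on the log2 scale against falls of -0.82 and -0.60 on Bt679, but without Bt407 replicate 1 labelled elt-2 RNAi the 6 h limit was -0.687 and the 2 strains no longer differed by the test. Reads of the RNAi trigger counted as elt-2 cannot be told apart from mRNA without reads along the gene, and that replicate 1 held 30.4 CPM against 23.3 CPM in the highest empty vector library. Knockdown strength and ELT-2 protein were not tested and stay open.

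The third is that at 12 h the libraries labelled elt-2 RNAi differed from empty vector one way on Bt679 (51 of 54 sperm markers higher, 24 of 28 oocyte markers and 6 of 6 vitellogenins lower) and another on Bt247 (0 sperm markers called, 16 oocyte markers higher and 1 lower, 2 vitellogenins higher and 1 lower), with no list call held under an estimated correlation. Earlier developmental time was tested over all genes, not in the germline alone. Of 3447 genes called over time on Bt407 in empty vector, 17.2% differed in the strain interaction as earlier time predicts. Across genes r was -0.377, but empty vector on Bt407 alone cannot date other groups, so time stays open. With RLE size factors at least 97.8% of called members of each of the 3 lists kept their call. The balance of all calls moved from 3120 and 2960 to 3572 and 2552, and a scaling error shared with TMM stays open. No biological explanation was tested: strain and dilution could not be separated, and both, with differences between the cultures, remain open.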

How the results depend on the processing

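The comparisons of strains within the libraries labelled elt-2 RNAi, with their alternatives, were chosen after the data were seen. No named gene that passed in both fits changed direction. Among all genes called in the model on all libraries, 1 changed sign on Bt247 against Bt407 at 12 h in empty vector when only the libraries compared were fitted, and at most 2 in 9 of the 174 fits that left out 1 library. The majority of calls turned from higher to lower or back in 6 of 23 comparisons with RLE size factors, 6 with DESeq2, 2 with no low-count filter, 2 with the replicate block, 7 with only the libraries compared and 10 with some library left out. With RLE size factors the RNAi comparison on Bt407 at 12 h turned to 2919 higher and 3437 lower, and time on Bt407 to 1828 and 1834. Of the named genes, 304 kept their side of the threshold with RLE size factors, 299 with DESeq2, 294 with no low-count filter, 271 with only the libraries compared and 310 with the replicate block, while 6, 5, 21, 23 and 2 lost their call and 5, 6, 0, 7 and 3 gained it. With 1 library left out at a time 2201 labels stayed, 164 calls were lost and 17 gained. Genes with few counts are limited by depth. Causes were not tested except where the construction shows them.

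Gene counts that moved by over 1.5 times were these. RLE size factors gave 11 for the Bt247 and Bt679 interaction at 6 h. No low-count filter gave 1 for Bt247 against Bt679 in empty vector at 6 h and 0 for that interaction. DESeq2 gave 35 and 676 for Bt247 against Bt679 in empty vector at 6 h and 12 h, 3178 for the Bt679 interaction at 6 h, 187 for the Bt247 and Bt679 interaction at 6 h and 197 for Bt247 against Bt407 at 12 h in the libraries labelled elt-2 RNAi. With only the libraries compared, which leaves fewer samples to estimate the spread, the counts were 419 for the RNAi comparison on Bt679 at 6 h, 0 and 3918 for Bt247 against Bt679 in empty vector at 6 h and 12 h, 2277 and 3441 for the interactions of Bt679 at 12 h and Bt247 at 6 h. They were 0 for the Bt247 and Bt679 interaction at 6 h and 1320 for time on Bt407. Against Bt407 in the libraries labelled elt-2 RNAi they were 282 and 5313 for Bt679 at 6 h and 12 h and 792 for Bt247 at 6 h. With an estimated correlation 6 of 345 list calls held. Over all 23 comparisons list calls gained and lost were 17 and 10 with RLE size factors, 64 and 9 with no filter and 3 and 2 with the block.

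Samples with the same replicate number did not deviate together over all pairs: their mean correlation was 0.021 over 198 pairs against -0.01 for other numbers, 30.8% against 28.5% of pairs were over 0.1, and in 2 of 17 comparisons (Bt247 against Bt407 in empty vector at 6 h and RNAi on Bt407 at 12 h) every pair was. With the replicate number as a block the count for Bt247 against Bt679 in empty vector at 6 h was 5, and no other count moved by over 1.5 times (2952 for the RNAi comparison on Bt679 at 6 h).

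Leaving out 1 library at a time gave these lowest and highest counts. For the libraries labelled elt-2 RNAi against empty vector they were 1934 to 2858 and 4905 to 8877 on Bt679 at 6 h and 12 h, 1868 to 3368 and 2838 to 3499 on Bt247, and 5495 to 6509 and 4977 to 5974 on Bt407. Against Bt407 in empty vector they were 5539 to 6402 and 5740 to 6688 for Bt679 and 6234 to 7207 and 8288 to 8934 for Bt247. Bt247 against Bt679 in empty vector gave 0 to 125 and 111 to 277. The interactions gave 895 to 2205 and 2328 to 5308 for Bt679, 1289 to 1973 and 3854 to 4745 for Bt247, and 0 to 1103 and 4221 to 7574 between Bt247 and Bt679. In the libraries labelled elt-2 RNAi, Bt679 against Bt407 gave 1130 to 3138 and 6000 to 8865 and Bt247 against Bt407 167 to 227 and 25 to 142, and time on Bt407 gave 1689 to 4048.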

Other observations

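The comparisons of strains within the libraries labelled elt-2 RNAi and the splits in this part were chosen after the data were seen. In those libraries vha-6 (-2.49 (SE 0.23) on the log2 scale), asp-1 (-1.72 (SE 0.18)) and vit-1 (-3.76 (SE 0.68)) were lower on Bt679 at 6 h than on Bt407. The kinase gene sek-1 (1.57 (SE 0.24)), upstream of PMK-1, and the phosphatase gene vhp-1 (0.97 (SE 0.14)) were higher. p38 and JNK pathway components gave 7 higher, 0 lower and 10 not called of 17 (8 and 0 adjusted over the list alone, camera adjusted p = 2.29e-07, and still adjusted p = 0.0298 with an estimated correlation). By edgeR 1007 genes were higher and 1526 lower. The total of 2533 was 1130 and 1605 without Bt679 replicates 2 and 3 and 1680, 1671 and 1454 without Bt407 replicates 1 to 3. At 12 h the intracellular pathogen response was lower on Bt679, pals-27 by -2.16 (SE 0.28) and pals-4 by -2.64 (SE 0.34). vit-6 (-4.36 (SE 0.36)), the eggshell gene cpg-2 (-0.94) and the argonaute gene sago-1 (-1.26) were lower too. Higher were cnc-4 (2.61), abf-5 (2.00) and the ribosomal gene rps-29 (1.05). For the intracellular pathogen response 4 of 40 members were higher, 27 lower and 9 not called (4 and 29 adjusted over the list alone, camera adjusted p = 1.03e-07, adjusted p = 0.278 with an estimated correlation). For epidermal antimicrobial peptides 14 of 17 members were higher, 0 lower and 3 not called (14 and 0 adjusted over the list alone, camera adjusted p = 5.87e-06, adjusted p = 0.239 with an estimated correlation). There were 4160 genes higher and 3992 lower, against 3702 and 4353 with RLE size factors.

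Bt247 gave fewer calls against Bt407 in these libraries. At 6 h 117 genes were higher and 259 lower (227 and 305 with DESeq2), with vha-6 (-1.94 (SE 0.22)), asp-1 (-1.16 (SE 0.18)) and vit-3 (-2.33 (SE 0.46)) among those lower. At 12 h 21 were higher and 63 lower, with vit-5 (-2.90 (SE 0.54)) and asp-1 (-0.86 (SE 0.18)) among the lower ones. Vitellogenins gave 0 higher, 6 lower and 0 not called of 6 (0 and 6 adjusted over the list alone, camera adjusted p = 5.06e-10, adjusted p = 0.0899 with an estimated correlation) at 6 h. The 376 genes at 6 h were 186, 187 and 226 without Bt247 replicates 1 to 3 and 220, 227 and 167 without Bt407 replicates 1 to 3. The 84 at 12 h were 25, 43 and 32 without Bt247 replicates 1 to 3 and 31 and 142 without Bt407 replicates 1 and 3, and DESeq2 called 75 higher and 122 lower.

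For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. In fits on the 6 libraries compared the real split and the highest other called 419 and 0 genes for RNAi on Bt679 at 6 h, and 5139 and 0 at 12 h. On Bt247 they called 2725 and 0, then 6418 and 0, and on Bt407 6932 and 0, then 4671 and 0. Bt679 against Bt407 in empty vector gave 5156 and 7541, and Bt247 6689 and 9197. The numbers were for time on Bt407 1320, Bt247 against Bt679 at 12 h 3918, and Bt679 in the libraries labelled elt-2 RNAi 282 and 5313, each with 0 in the highest other. Bt247 in those libraries gave 792 against 225 and 61 against 14. In all of these 1 of the 10 splits was as large. For Bt247 against Bt679 in empty vector at 6 h all 10 were: the real split called 0 genes and that of Bt679 replicate 1 with Bt247 replicates 1 and 2 against the rest 1346. That split is the strain split with Bt679 replicate 1 and Bt247 replicate 3 exchanged. It points to a structure that the strain labels do not follow, and an exchange of labels was not tested. Deviations of samples with numbers 1, 2 and 3 correlated at 0.588, -0.059 and 0.68 between these groups, and the count with the replicate block was 5.

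Other lists are given by how many of the 19 comparisons fixed beforehand camera called higher and lower. None of them held with an estimated correlation, the smallest adjusted p being 0.0792 for caenacins and antibacterial factors (1 and 1). The numbers were 0 and 2 for GATA factors, 1 and 5 for C-type lectins, 4 and 7 for saposin-like proteins, 3 and 6 for pore-forming toxin response genes, 0 and 0 for toxin resistance glycolipid genes, 3 and 4 for the hypoxia and sulfide response, 1 and 2 for heat shock chaperones, 2 and 0 for autophagy genes, 2 and 2 for metallothioneins, 4 and 2 for epidermal antimicrobial peptides, 1 and 2 for DAF-16 class I genes, 2 and 1 for cytochrome P450s, and 0 and 1 for UDP-glucuronosyltransferases. They were 4 and 4 for glutathione S-transferases, 3 and 5 for fatty acid synthesis, 2 and 8 for fatty acid breakdown, 2 and 1 for lipid-binding proteins, 0 and 3 for body wall muscle markers, 4 and 7 for ribosomal proteins, 2 and 6 for the respiratory chain and 4 and 9 for RNAi machinery. Of the thaumatins 2 members were tested and no list test was made. In 3 list calls the median had another sign than the mean and the test: C-type lectins for RNAi on Bt407 at 12 h (0.06 and -0.44) and for Bt247 against Bt407 in empty vector at 6 h (0.06 and -0.24, the median being 0 with low-count members at their bound), and saposin-like proteins in the Bt247 interaction at 6 h (-0.04 and 0.48).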
